A study of Mus musculus with 2 samples.

How the data were processed

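Cochlear ducts of FVB/NJ mice heterozygous for Fbxo2VHC were dissected at 90 days of age, pooled from 3 animals per sex and processed to nuclei, and Venus-positive nuclei were sorted before droplet capture, per the labels' protocols. The deposited values are raw counts of unique molecular identifiers (UMIs) per gene and barcode, which the authors made with Cell Ranger, version 4 per the file headers, against mm10 per the submitters' processing notes. Those notes also name Seurat 4.3.0, but the deposited counts carry no cell annotation used here, and the annotation release used for counting is not given in the sources used here. Each matrix holds 32285 genes and all barcodes, 830927 in the male and 724271 in the female library, most of them empty droplets. Symbols that occur more than once were kept apart by identifier. Coordinates are from the GENCODE annotation of GRCm38, the same assembly as mm10, matched by gene identifier.

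Barcodes with at least 500 detected genes were taken as nuclei, 2940 in the male and 2030 in the female library. Those with more than 5% mitochondrial UMIs were removed, 625 and 129. Scrublet's automatic threshold marked 0 doublets in either library, so the highest-scoring barcodes were removed at the loading rate of 0.8% per 1000 nuclei, 43 and 29, and doublets within a class cannot be excluded. This left 2272 male and 1872 female nuclei. Counts were scaled to 10000 per nucleus and log-transformed, 2000 variable genes outside the compared gene lists were reduced to 30 principal components, and nuclei were clustered with the Leiden method at resolution 1.0 on a shared-neighbour graph of 20 neighbours (scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, Python 3.11.15). The libraries were clustered together without correction.

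Clusters were named from 24 marker lists written before the data were examined. A list was a candidate for a cluster if at least 3 of its markers were raised there and in at least 5% of its nuclei, with a mean standardised level of at least 1. A stricter rule was set after the data were seen. It asked for a marker among the first 10 of the cluster's leading genes, or for 2 among the first 50, and refused a name if another class had more markers among the first 10. It also refused clusters that matched the red blood cell list, and clusters of low UMI count without a marker among the first 10. Of 28 clusters, 16 were named and 12 were not. The stricter rule kept out 8 clusters, which held 23.7% of the male and 23.1% of the female nuclei, and the other 4 had no candidate list. One of the 8, with 24 nuclei in each library, matched the Deiters and pillar cell list and was added back as an alternative. Names are likenesses, and a difference from the study may come from these rebuilt names. The hair cell-like class joins an inner and an outer hair cell-like cluster. Classes needed at least 20 nuclei in each library, which 14 classes with 2486 nuclei met.

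UMI counts were summed per library and class. The 28 sums were fitted with edgeR 4.0.16 (quasi-likelihood, TMM scaling, its expression filter; limma 3.58.1, R 4.3.3) with class and library as terms, since the classes of 1 library come from the same animals. The fit covered 11905 genes with 13 residual degrees of freedom and a common dispersion of 0.0386. The first contrast took the mean of the hair cell-like and 2 supporting cell-like classes minus the mean of the marginal, intermediate and basal cell-like classes; the second took hair cell-like minus supporting cell-like classes. Residual degrees of freedom come mostly from the many classes of 2 libraries, so p-values describe differences between classes relative to how classes varied between these 2 pools. P-values were adjusted by Benjamini-Hochberg over all genes tested, at a threshold of 0.05, and again over each list alone. Gene lists, 15 in number, were fixed with the marker lists: age-related hearing loss, hereditary deafness, mechanotransduction, stereocilia, ribbon synapse, potassium and endocochlear potential, tectorial membrane, Notch and progenitor, Y-linked, X-escape, sex hormone, circadian, stress, antioxidant and mitochondrially encoded genes. The lists were written from general knowledge and share members. Class markers were left out of list counts. List tests used camera with a preset correlation of 0.01, and again with an estimated correlation, adjusted over the lists.

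The named genes followed a rule fixed at the same time. For the class contrasts, it took the 10 largest increases and the 10 largest decreases among age-related and deafness genes past the threshold with the same direction in both libraries, and up to 2 of each from the other lists. Some genes that this rule or the lists hold are not reported here. For levels it took the 10 largest ratios of the highest class to the mean of the others. For male against female it took the Y-linked and X-escape genes and the 10 genes with the highest and the 10 with the lowest ratio. Those needed at least 100 UMIs, a ratio on the same side in every class, and a mean of at least 2-fold. Male to female ratios added 0.5 counts in proportion to the size of each sum, a choice made after seeing that a flat 0.5 favoured the smaller sums. No p-value is given between the libraries of each sex. Levels are CPM of the summed counts. In the class contrasts, genes with 1 to 3 counts on a side are given as a ratio with an exact 95% counting interval, and 0 counts as a limit of 3 counts. Intervals cover counting error only.

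Near-empty droplets of 10 to 100 UMIs, 66083 in the male and 89464 in the female library with 4110304 and 2782444 UMIs, served as the profile of free RNA. Alternatives were set for the gene minimum (300, 1000), the mitochondrial limit, doublet removal, the resolution (0.5, 2.0), the genes used for clustering, centring within libraries, size factors, DESeq2 1.42.0, the expression filter, the library term, subtraction of 10% free RNA, each library alone, and thinning to 1000 UMIs, which left out 61 male and 55 female nuclei. On simulated counts with 100 genes changed by 2-fold and 100 by 4-fold among 11905, the first contrast made 13 false calls among 168 and the second 2 among 91. Before the change, each simulated gene had the same level in all classes. Inner and outer hair cells were not compared, because the planned minimum of 20 nuclei was not met.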

Results

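Nuclear RNA was measured in the cochlear ducts of mice 90 days old that carried 1 copy of Fbxo2VHC, an allele used to label cells of the inner ear with Venus fluorescence. Venus-positive nuclei were sorted to enrich hair cells, the mechanosensory cells of the organ of Corti, and the supporting cells that surround them. There was 1 male and 1 female library, each from the pooled ducts of 3 animals, so the libraries are the only replicates. The male library held 20698871 UMIs, 57.2% of them in the 2272 nuclei kept, and the female library held 15577023 UMIs, 72.6% of them in 1872 nuclei. The median nucleus had 3777.5 UMIs and 1839 detected genes in the male library, and 4572 UMIs and 2189 genes in the female library. The series asks in which tissue of the cochlea, sensory epithelium or stria vascularis, genes linked to age-related hearing loss are expressed, and it provides both sexes.

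The first question is which cell types the sorted nuclei came from. Hair cell-like nuclei made up 2.77% of the male library (63 nuclei, exact binomial 95% interval 2.14% to 3.53%) and 2.56% of the female library (48 nuclei, 1.90% to 3.39%). Supporting cells came as a class like Deiters and pillar cells, with 3.74% and 5.07% of the male and female libraries, and a class like inner border and phalangeal cells, with 4.71% and 3.37%. The stria vascularis, the ion-pumping epithelium of the lateral wall, came as marginal cell-like nuclei (4.84% and 5.61%), intermediate cell-like nuclei, which are melanocytes (6.25% and 4.49%), and basal cell-like nuclei (4.31% and 6.57%). At the main settings the most frequent named class was like inner sulcus and interdental cells, with 12.4% and 9.99%. With at least 1000 detected genes, fibrocyte-like nuclei had the larger share in the female library. Nuclei like Reissner's membrane, the sheet that closes the duct towards the scala vestibuli, were 8.98% of the male library (interval 7.83% to 10.2%) and 3.79% of the female library (2.97% to 4.76%). Fibroblast-like nuclei were 3.65% and 1.44%, and fibrocyte-like nuclei 2.82% and 5.88%, again with intervals that did not overlap. The fibrocyte-like shares rose to 8.01% and 9.99% at a clustering resolution of 0.5, and to 6.82% and 8.83% with at least 1000 detected genes, and in both cases their intervals overlapped (6.93% to 9.20% and 8.67% to 11.4%, and 5.75% to 8.02% and 7.52% to 10.3%). The basal cell-like intervals, 3.52% to 5.23% and 5.49% to 7.79%, did not overlap either, but did at resolution 0.5 (4.92% to 6.90% and 6.33% to 8.76%) and with genes centred within libraries. Among the clusters without a name, 2 whose closest list was fibrocyte held 180 and 82 male and 34 and 38 female nuclei. Neither had a fibrocyte marker among its first 50 leading genes. The larger was led by Rarres1 and Emilin2, which are on the marker list of tympanic border cells, so it cannot be counted as fibrocytes. The Hensen and Claudius cell-like shares went from 1.45% and 2.30% to 8.54% and 9.72% with all variable genes used for clustering. Outer sulcus and root cell-like nuclei were 1.76% and 1.60%, glia-like nuclei 2.68% and 3.53%, endothelial-like nuclei 1.67% and 1.34%, and macrophage-like nuclei, too few to test, 0.704% and 0.588%. Clusters left without a name held 37.3% of the male (35.3% to 39.3%) and 41.9% of the female nuclei (39.6% to 44.2%), but the intervals overlapped at resolution 0.5 and 2.0, with at least 1000 detected genes and with all variable genes used for clustering. Without a mitochondrial limit the direction turned, with 46.7% male and 43.1% female, and the intervals overlapped. These shares depend on the Venus sort and on how the classes were rebuilt, the intervals cover counting error only, and a difference between 2 libraries has no replicate check. RNA of Fbxo2, the gene that drives the sort, was highest in the Hensen and Claudius cell-like class, at 1374 ± 175 CPM (SD, n = 2), beside 392 ± 57.6 CPM in hair cell-like nuclei. Near-empty droplets held Fbxo2 at 1401 CPM in the male and 949.5 CPM in the female library, so free RNA of this gene was abundant.

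**Figure D1:**
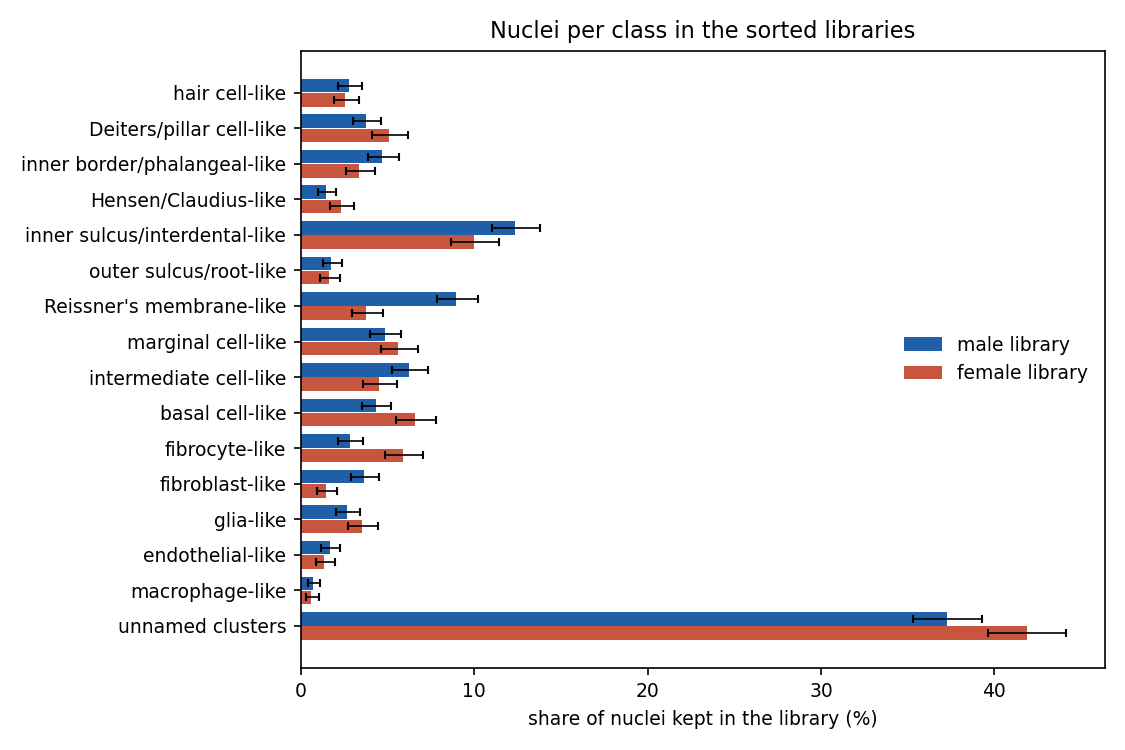
Share of the nuclei kept in each library (horizontal axis, percent) for each class, with the male library in blue and the female library in red; bars start at 0 and error bars are exact binomial 95% intervals, which cover counting error only. The Reissner's membrane-like bars, 8.98% and 3.79%, have intervals that do not overlap, while the hair cell-like bars, 2.77% and 2.56%, do.

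Genes linked to hearing loss were more often higher in the sensory epithelium than in the stria vascularis. Of 28 tested genes from the age-related hearing loss list that were not used to name classes, 12 were higher in the sensory classes. Another 4 were higher in the stria classes, and 1 of these 4, Grm8, had the opposite sign in the male library. None of the 4 had its highest mean level in a stria class. Nid2 (36.3 CPM) and Mmp2 (87.1 CPM) were highest in fibroblast-like nuclei. Acadvl (39.2 CPM) and Grm8 (33.9 CPM) were highest in outer sulcus and root cell-like nuclei, but the highest class of Grm8 differed between libraries. Of 69 genes of hereditary deafness, 27 were higher in the sensory classes and 11 in the stria classes. Ush1c, which codes for the harmonin scaffold of the hair bundle, reached 345 ± 60 CPM (SD, n = 2) in the sensory classes and 24.7 ± 16.8 CPM in the stria classes. On the stria side, Hgf, the gene of hepatocyte growth factor, had 71.0 ± 1.62 CPM against 3.66 ± 2.68 CPM in the sensory classes. This stria level came mostly from marginal cell-like nuclei, at 202.9 CPM beside a mean of 10.7 CPM in the other classes.

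These calls came from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 11905 genes, of which 2020 were higher in the sensory and 2212 in the stria classes. Adjusted over the list alone, 14 age-related genes were higher and 4 lower, and 32 deafness genes were higher and 12 lower. The camera test of whether a list stands apart from the other genes gave an adjusted p of 0.000651 for the age-related list, and the call was lost with adjusted p = 0.0665 with an estimated correlation. For the deafness list the adjusted p was 7.52e-06, and the call held at 0.0236 with an estimated correlation. The median ratio of CPM summed over each side was 1.00 on the log2 scale for the age-related list and 0.75 for the deafness list, with 0 genes that had no count on a side. With the hair cell-like class left out, an alternative chosen after seeing the data, 10 age-related genes were higher and 4 lower, and 20 deafness genes were higher and 11 lower, while the fitted median of the deafness list went from 0.66 to -0.0048. The 4 age-related genes lower became 2 without a limit on the mitochondrial share, and the 11 deafness genes lower became 7 with the free RNA profile subtracted.

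Among the 10 hearing loss genes with the largest increase, Ush1c (chromosome 7, 46195350 to 46238503, GRCm38) had a log2 fold change of 4.09 ± 0.24 (SE) and an adjusted p of 1.87e-12 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Cldn14, a tight junction claudin, rose by 3.45 ± 0.28, and Tmprss3, a transmembrane serine protease, by 3.32 ± 0.24 on the log2 scale. Cldn14 was at 4.29 in the male and 2.95 in the female library alone. Msrb3, a methionine sulfoxide reductase, rose by 3.30 and P2rx2, an ATP-gated channel, by 2.81. Cabp2 (2.76) and Lhfpl5 (2.76), a calcium-binding protein of the hair cell synapse and a subunit of the transduction channel complex, were close to each other. From the age-related list, Ildr1, a tricellular junction protein, rose by 2.74 and Clic5 by 2.69. Fscn2, an actin cross-linker, had 70 counts in the sensory and 2 counts in the stria classes, a ratio of summed CPM of 38.1 with a counting interval from 10.2 to 320. Cabp2, Lhfpl5 and Fscn2 were highest in hair cell-like nuclei, at 289.6, 120.5 and 58.8 CPM. Their means in the other classes were 3.4, 4.0 and 1.3 CPM, so their sensory level came mostly from the hair cell-like class. Lhfpl5 lost its call under 2 and Cabp2 under 1 of 17 alternative settings, and Fscn2 under 1 of 16.

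The 10 hearing loss genes with the largest decrease, which means the higher level in stria, included Pax3, a melanocyte transcription factor, with 15 counts in the sensory and 1032 in the stria classes. Its summed CPM was 63.3 times higher in stria, with a counting interval of 38.2 to 114, and 1 sensory class had no Pax3 count. Pax3 was highest in intermediate cell-like nuclei, at 791 CPM beside a mean of 7.48 CPM in the other classes. Fitted fold changes average the classes of a side on the log scale, so they can differ from ratios of CPM. Tnc had 1 sensory and 16 stria counts, a ratio of 14.7 in favour of stria (2.29 to 617) that rests on the female library (0 and 14 counts; male 1 and 2, 0.762 and 0.793 CPM), and Nid2 had 6 and 51 counts, a ratio of 7.82 (3.36 to 22.3). Hgf had a log2 fold change of -2.29 ± 0.65, Col2a1 -2.01 ± 0.55 and Mmp2, a gelatinase, -1.67 ± 0.45. Col4a4 (-1.22), Tbc1d24 (-1.22), Acadvl (-1.04) and the connexin gene Gjb6 (-0.93) made up the rest. The log2 ratio of the male library alone was smaller than that of the female for Hgf (-0.87 and -2.44), Col2a1 (-0.89 and -2.27) and Col4a4 (-0.47 and -1.85). Of 17 alternative settings, 10 ended the call of Tnc, 6 that of Pax3, 3 that of Hgf, and 1 each those of Col2a1, Mmp2 and Col4a4. Baiap2l2, Clrn2, Strc, Bsnd and Otol1 had a class without counts and a p near 1 for that reason, so their missing calls carry no information.

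**Figure D2:**
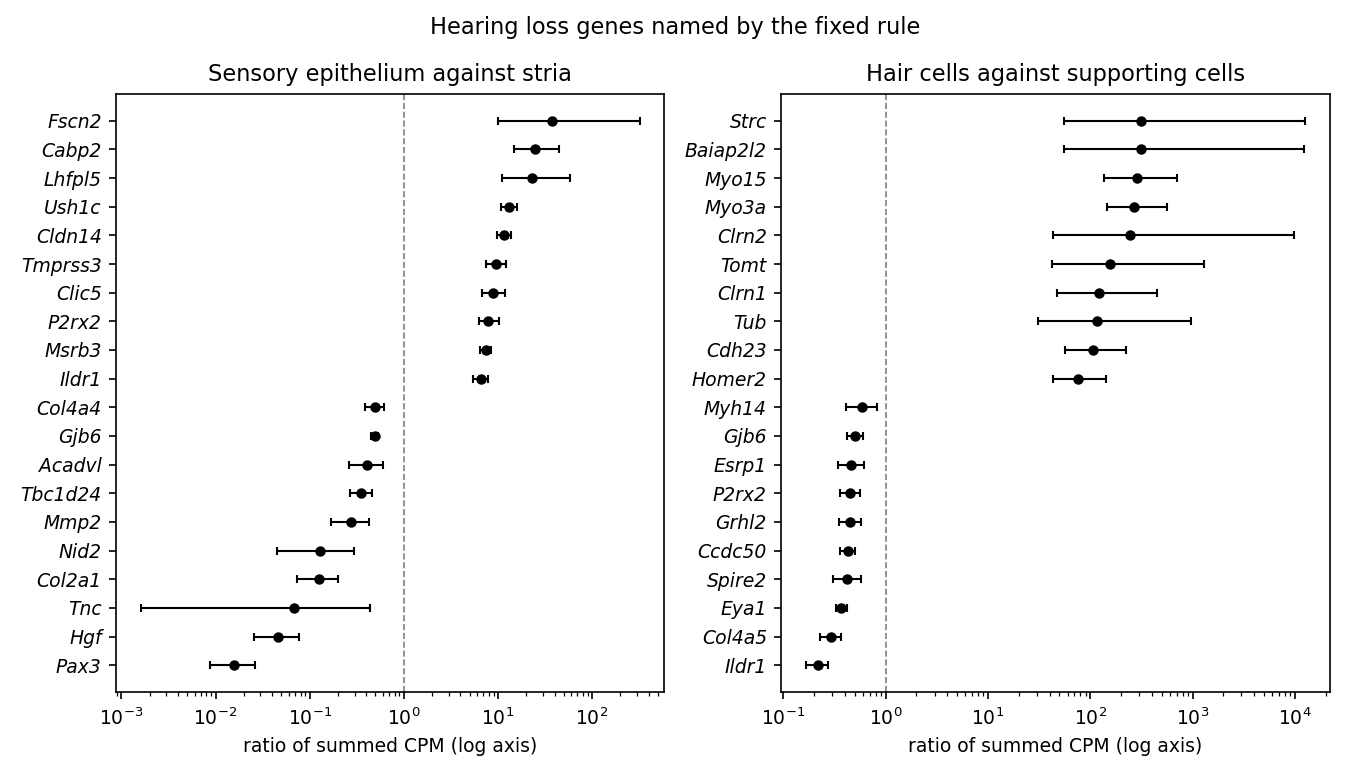
Ratio of summed CPM (horizontal log axis) for the hearing loss genes named by the fixed rule, sensory epithelium against stria on the left and hair cells against supporting cells on the right; points are both libraries pooled, and bars are 95% counting intervals. Fscn2 reaches 38.1 on the left and Ildr1 changes sides, at 6.54 on the left and 0.215 on the right.

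Among the other fixed lists, hair bundle genes stood higher in the sensory classes and antioxidant genes in stria. In the sensory classes, 10 of 18 stereocilia genes were higher, among them Pls1, an actin bundler, with a log2 fold change of 2.77, and the camera adjusted p was 9.90e-05. Of 5 mechanotransduction genes, 2 were higher, Ush1c and Lhfpl5 (camera adjusted p = 0.00414), and of 12 ribbon synapse genes, 4 were higher, among them Rims2 at 2.63, without a list call (camera adjusted p = 0.0912). No gene of these lists was lower by edgeR with adjustment. At an unadjusted p under 0.05 the counts lower were 0, 0 and 1 in that order, and DESeq2 called 0 in each. These counts rested in part on the hair cell-like class: with it left out, an alternative chosen after seeing the data, 5 stereocilia genes were higher and 2 lower, 1 mechanotransduction gene was higher and 1 lower, and 1 ribbon synapse gene was higher and 3 lower. Of 12 potassium and endocochlear potential genes, 6 were higher in stria and 3 in the sensory classes. Slc12a2, a potassium importer (log2 fold change -3.39 ± 0.22), stood at 2218 ± 163 CPM (SD, n = 2) in stria, while Slc12a7 (2.44) and Kcnj16 (1.78) were higher in the sensory classes (camera adjusted p = 0.0625).

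Notch pathway and progenitor genes were higher in the sensory classes for 5 of 8 members, among them Lfng (3.35) and Heyl (1.72), and lower for Notch2 (-2.08), without a list call (camera adjusted p = 0.494). Of 13 antioxidant genes, 7 were higher in stria, among them Nfe2l2 (-1.59), a regulator of the antioxidant response, and Gpx1 (-1.12), at a camera adjusted p of 0.0185 that stayed at 0.0467 with an estimated correlation. None was higher in the sensory classes by edgeR after adjustment, 1 was at an unadjusted p under 0.05, and DESeq2 called 0. The circadian list went both ways, with 6 of 16 genes higher and 5 lower; Npas2 (3.03) and Arntl (1.78), partners in the clock's activating complex, were higher, and the repressor Bhlhe41 (-2.89) and Hlf (-1.42) were lower (camera adjusted p = 0.414). Of 5 members of the sex hormone list, Srd5a1, a steroid reductase gene, was higher (106 sensory and 17 stria counts) and Esrrg (-2.07) and Esrra (-1.08) were lower (camera adjusted p = 0.494). These calls are about list members, and hormone action was not measured. Of 7 tectorial membrane genes, 3 were lower, with Col2a1 and Col9a1 (-1.13) named (camera adjusted p = 0.341). Hspa8 was lower (-0.89) in the stress list of 5 genes (camera adjusted p = 0.494). The 4 Y-linked, 8 X-escape and 13 mitochondrially encoded genes gave 0 calls by edgeR and by DESeq2; at an unadjusted p under 0.05 the counts were 0, 1 and 0. Without a mitochondrial limit, 12 of the 13 mitochondrially encoded genes were higher in the sensory classes. Rims2 was at 3.48 in the male and 1.73 in the female library alone, and Hspa8 at -0.40 and -1.37. Of 17 alternative settings, 4 ended the call of Gpx1, 3 that of Col9a1, 2 that of Hspa8, and 1 each those of Rims2 and Srd5a1.

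Within the sensory epithelium, hair cell-like nuclei were set against the 2 supporting cell-like classes that the sort was also meant to enrich. Hair bundle and synapse genes separated the sides: 17 of 18 stereocilia genes and 12 of 12 ribbon synapse genes were higher in hair cell-like nuclei. The class was named by markers of the same kind, among them Tmc1, Loxhd1 and Otof, so the naming largely set this outcome. It is a check of the class name. The age-related and deafness lists share members with the stereocilia list, among them Baiap2l2 and Strc. Of the 28 age-related genes, 13 were higher in hair cell-like and 3 in supporting cell-like nuclei, and of the 69 deafness genes, 31 and 9. Myo15 (chromosome 11, 60469339 to 60528369), the motor that carries proteins to stereocilia tips, had 816 ± 196 CPM (SD, n = 2) in hair cell-like and 2.06 ± 0.628 CPM in supporting cell-like nuclei. Supporting cell-like nuclei held more Ildr1, with 295 ± 52.0 CPM against 66.6 ± 1.72 CPM.

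Over all genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 1538 higher and 1038 lower in hair cell-like nuclei. Adjusted over the list alone, the age-related counts were 15 higher and 3 lower, and the deafness counts 32 higher and 9 lower. Camera gave an adjusted p of 1.01e-06 for the age-related list (0.0218 with an estimated correlation) and 1.33e-12 for the deafness list (0.00229). The stereocilia list had 7.68e-33 (1.57e-06) and the ribbon synapse list 5.85e-16 (0.000134) in the same order, values that the naming of the class largely set. Of 5 mechanotransduction genes, 4 were higher (camera adjusted p = 7.06e-10). In these 3 lists edgeR called 0 genes lower after adjustment and 0 at an unadjusted p under 0.05, as did DESeq2. On simulated counts with known changes, this contrast recovered 22.0% of genes changed by 2-fold and 67.0% of those changed by 4-fold, so moderate differences can be missed. The sensory against stria contrast recovered 63.0% and 92.0%. Before the change, each simulated gene had the same level in all classes, so these rates may not hold for genes confined to few classes.

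Myo15 had 899 hair cell-like and 7 supporting cell-like counts, a ratio of summed CPM of 285 with a counting interval of 138 to 711. Myo3a, another stereocilia motor, rose by 8.19 ± 0.43 on the log2 scale (adjusted p = 1.08e-13, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), Clrn1 by 6.81 ± 0.55, Cdh23, the tip link cadherin, by 6.54 ± 0.45, and Homer2 by 6.05 ± 0.34. Baiap2l2, Strc and Clrn2 each had 1 supporting cell-like count, with 140, 142 and 111 hair cell-like counts. Their ratios were 311 (54.9 to 12360), 315 (55.7 to 12540) and 246 (43.3 to 9820), and the call of Clrn2 was lost under 1 of 16 alternative settings. Tub and Tomt each had 2 supporting cell-like counts, and their ratios were 115 (31.2 to 966) and 154 (41.9 to 1287). In the ribbon synapse list, Cabp1 had 79 against 1 count, a ratio of 175 (30.6 to 7014), and Erc2, an active zone protein, rose by 6.76 ± 0.38.

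The 10 largest decreases in hair cell-like nuclei among the hearing loss genes were those of Ildr1 (log2 fold change -2.19 ± 0.40), Col4a5 (-1.80), Eya1 (-1.53), Ccdc50 (-1.38), Spire2 (-1.30), Grhl2 (-1.30), Gjb6 (-1.20), Esrp1 (-1.14), P2rx2 (-1.03) and Myh14 (-0.98). Of 16 alternative settings, 4 ended the call of Spire2, 2 that of Myh14, and 1 each those of Grhl2 and Gjb6. Ildr1 and P2rx2 were thus above stria in the sensory classes as a whole, and above hair cell-like nuclei in supporting cell-like nuclei. Of 12 potassium genes, 4 were higher, among them the channels Kcnma1 (6.67) and Kcnn2 (4.62), and 3 lower, among them Slc12a7 (-2.21) and Kcnj16 (-1.75), with a camera adjusted p of 0.474. Of 8 Notch pathway and progenitor genes, 5 were lower, among them Lfng (-3.44) and Hes1 (-3.10), and the ligand gene Jag2 was higher (2.21). The camera adjusted p was 0.0100, and the call was lost with adjusted p = 0.0737 with an estimated correlation. Of 16 circadian genes, 5 were lower, including Ciart (-1.99), and Npas2 was higher (0.99), a call lost under 8 of 16 alternative settings. Bhlhe40 had 2 hair cell-like and 38 supporting cell-like counts, a ratio of 8.56 in favour of supporting cells (2.21 to 73.2). The male library carries it (0 and 30 counts), as the female had 2 and 8 counts (4.11 and 5.24 CPM); its call was lost under 4 of 16 settings and that of Ciart (-2.23 in the male and -0.75 in the female library alone) under 1. The circadian list had a camera adjusted p of 0.0265, lost with adjusted p = 0.0737 with an estimated correlation.

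In the smaller lists, Srd5a1 was higher in hair cell-like nuclei (log2 fold change 3.39), and so was Nfe2l2 (2.41), the opposite of its direction against stria; camera gave adjusted p values of 0.685 and 0.980 for their lists. Col9a3 was lower (-1.27) as the 1 call among 7 tectorial membrane genes (camera adjusted p = 0.685). The Y-linked, X-escape, stress and mitochondrially encoded lists had 0 calls by edgeR, with 0, 1, 1 and 4 genes at an unadjusted p under 0.05; DESeq2 called 0, 0, 0 and 1. Without a mitochondrial limit, 12 mitochondrially encoded genes were higher in hair cell-like nuclei.

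The comparison of inner with outer hair cells was planned only for at least 20 nuclei of each kind in each library. The inner hair cell-like cluster had 20 male and 14 female nuclei, so it was not run.

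The next question was in which of 14 classes each age-related gene had its highest level. Of 41 genes, 37 reached a mean of 10 CPM in a class. With class markers included, 19 of them were highest in the sensory classes, 6 in the stria and 12 elsewhere. Leaving out class markers, 30 remained, of which 17 were highest in the sensory epithelium, 13 of them in hair cell-like nuclei, 3 in the stria and 10 in other classes. In 24 of the 30 the highest class was the same in both libraries. Among 14533 other genes, 21.8% were highest in the sensory classes, 10.4% in hair cell-like nuclei and 16.6% in the stria. Of 70 hereditary deafness genes counted in the same way, 38 were highest in the sensory classes, 12 in the stria and 20 elsewhere. With class markers included, 98 were counted, with 50, 20 and 28 in the same order. No test was made of these counts.

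Clrn2 (chromosome 5, 45453751 to 45464149), a hair bundle membrane protein, had the largest ratio among genes with counts in other classes: 97.4 ± 9.82 CPM (SD, n = 2) in hair cell-like nuclei, 462 times the mean of the other classes. Klhdc7b, with 12.4 CPM in hair cell-like nuclei and 0 in the other classes, has no finite ratio. Near-empty droplets held Clrn2 at 1.95 CPM in the male and 5.03 CPM in the female library, above its mean of 0.211 CPM in the other classes. Clrn2 had 115 UMIs over the tested classes, so its ratio rests on very few counts outside hair cell-like nuclei. No counting interval was computed for these ratios. Baiap2l2 followed with 125 ± 14.5 CPM and a ratio of 169, Tub with 97.9 ± 59.2 CPM and 90.6, Crip3 with 42.9 ± 5.42 CPM and 50.2, Fscn2 with 58.8 ± 12.7 CPM and 44.3, and Cdh23 with 435 ± 121 CPM and 39.8, all in hair cell-like nuclei. Baiap2l2 and Tub had 153 and 120 UMIs over the tested classes, so their ratios too rest on few counts elsewhere. Crip3 stood at 18.0 CPM in the male near-empty droplets, so part of its low level elsewhere lies within the range of free RNA. Slc26a5, Loxhd1, Tyr and Esrrb also ranked among the first 10, with ratios of 209, 166, 95.5 and 56.8, but they had served as class markers and are not results. Stria classes held the highest level of Phldb1 (85.2 CPM), Sik3 (545.8 CPM) and Zfp318 (46.5 CPM), each in basal cell-like nuclei. Sik3 and Zfp318 were only 1.59 and 1.39 times the mean of the other classes, and their highest class differed between the libraries.

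**Figure D3:**
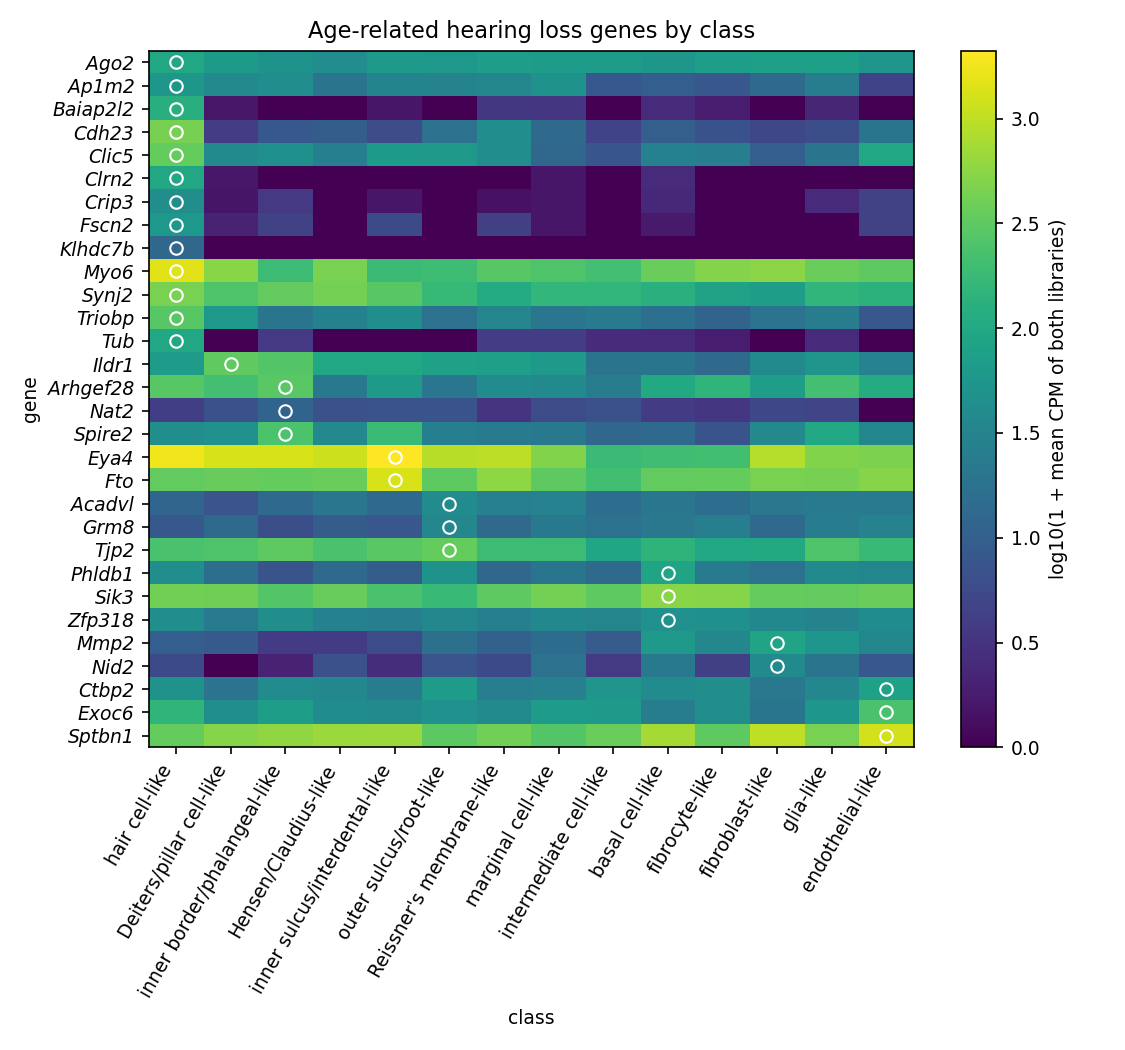
Mean CPM of both libraries on a log10 scale (colour, log10 of 1 + CPM) for the 30 age-related hearing loss genes that were not class markers and reached 10 CPM (top to bottom) in 14 classes (left to right); a white circle marks the class with the highest mean. The circles of 17 genes lie in the 3 sensory classes on the left, and those of 3 genes in the stria classes.

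Male and female libraries were compared as values only, because each sex had 1 library. The Y-linked genes marked the male library in 14 of 14 classes. Uty reached 281 CPM (exact Poisson 95% interval 269 to 293), Eif2s3y 116, Ddx3y 96.5 and Kdm5d 48.7 CPM over the tested classes. In the female library Uty had 5 and Ddx3y 27 UMIs, Kdm5d had 1 UMI against 352 in the male library, and Eif2s3y had 0 UMIs, which makes it at least 258-fold higher in the male library against a limit of 3 counts. The female library held 1023 CPM of Xist, the RNA that silences an X chromosome (interval 999 to 1047), against 5.53 CPM in the male (3.95 to 7.53), and 463 against 9.82 CPM of its antisense partner Tsix. The X-linked genes Kdm6a (230 against 108 CPM), Ddx3x (123 against 59.9), Kdm5c (113 against 77.3), Pbdc1 (48.2 against 22.9), 5530601H04Rik (37.6 against 27.5) and Eif2s3x (32.1 against 18.0) also had the higher value in the female library. Ddx3x and Ddx3y are similar copies, and Xist and Tsix overlap on opposite strands, so the values of these 4 genes are uncertain.

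Outside the Y-linked and X-escape lists, the rule for large ratios named 6 genes higher in the male library in 14 of 14 classes. These were 4930469K13Rik (47.6 against 2.55 CPM), Ubb, a ubiquitin gene (219 against 24.0), Asmt (16.9 against 1.65), Rpl35 (113 against 21.5), Taco1 (39.5 against 11.6) and Leng9 (104.5 against 40.1). On the female side it named Bc1, a small RNA of neurons (122 against 1.80 CPM), Prl, which codes for the pituitary hormone prolactin (102 against 1.66), the haemoglobin gene Hba-a2 (45.7 against 3.32), Gm10801 (318 against 30.4), Rpl10-ps3 (62.2 against 4.29), Gm2000 (93.3 against 9.40), Gm10719 (21.9 against 1.66) and Gm10718 (18.9 against 0.83). Ubb, Rpl35, Rpl10-ps3 and Gm2000 belong to families with near-identical copies or pseudogenes and are uncertain. Whether the other genes named here, Hba-a2 and the Gm genes among them, have such copies was not checked. Ubb stood at 612 CPM in the male and 41.0 CPM in the female near-empty droplets, and Prl at 48.9 and 341 CPM. Rpl35 in the male near-empty droplets (366.6 CPM), and Bc1 (545.2), Gm2000 (184.7), Hba-a2 (105.7) and Rpl10-ps3 (96.3 CPM) in the female ones, also stood above their level in nuclei, so free RNA is not separated from these ratios. With every nucleus thinned to 1000 UMIs, 5 of the 10 male and 4 of the 10 female genes were named again.

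**Figure D4:**
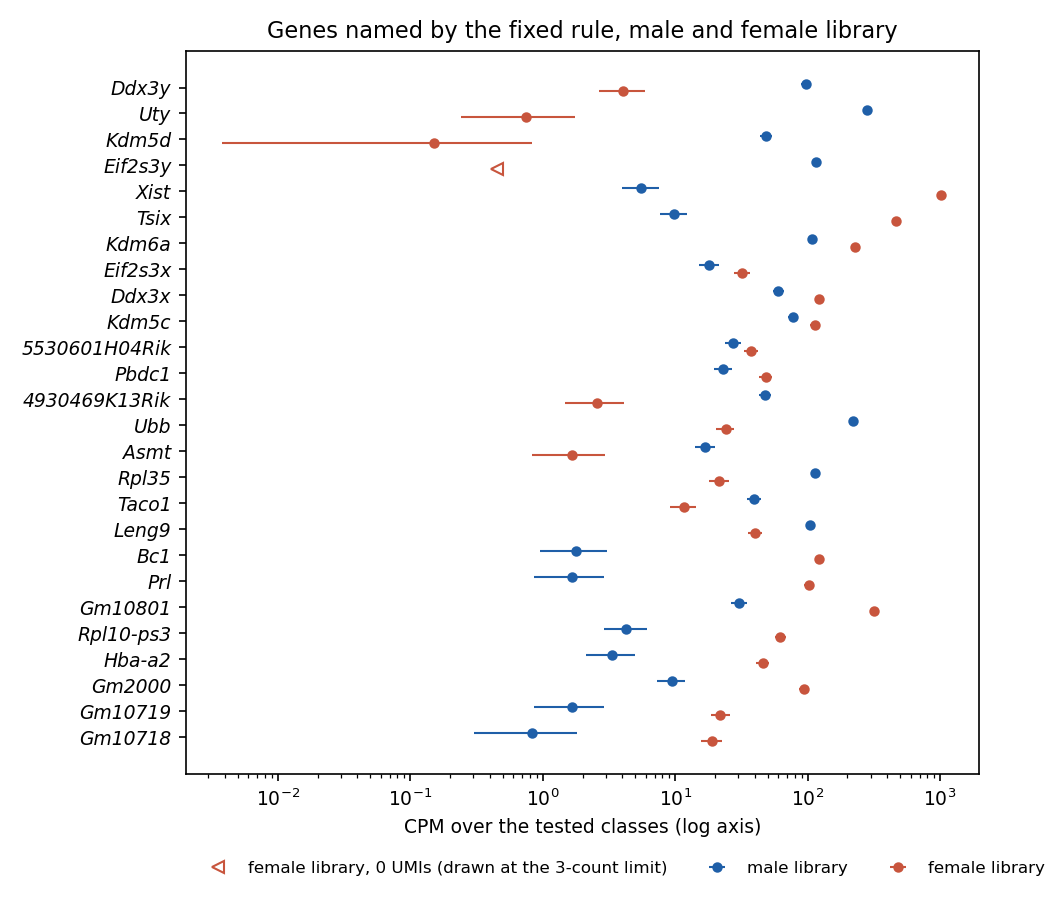
CPM over the tested classes (horizontal log axis) of the genes named by the fixed rule, male library in blue and female library in red, with exact Poisson 95% intervals that cover counting error only. Xist lies at 1023 CPM in the female and 5.53 CPM in the male library; the open triangle of Eif2s3y marks 0 UMIs, drawn at the limit of 3 counts.

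For gene lists, the median log2 ratio of male to female was set among 10000 random lists of equal expression, as a description of these 2 libraries. The random lists were matched on total UMIs, not on how few classes express a gene, so their percentiles can compare unlike genes. The median of all 11894 genes with at least 100 UMIs was -0.07. Hereditary deafness genes had a median of -0.21 (percentile 0) and age-related genes -0.18 (percentile 4.01). Ribbon synapse (-0.84), mechanotransduction (-0.67), sex hormone (-1) and mitochondrially encoded genes (-0.55) lay at percentile 0, and stereocilia genes (-0.26) at 0.63. With each gene read in its highest class only, an alternative chosen after seeing the data, the medians shrank to -0.29 for ribbon synapse, -0.18 for mechanotransduction and -0.06 for sex hormone genes, beside -0.05 for all genes. They were -0.14 for deafness, -0.13 for age-related, -0.31 for stereocilia and -0.45 for mitochondrially encoded genes. The potassium (-0.17, percentile 8.88), antioxidant (-0.20, 8.05), tectorial membrane (0.01, 88.2), Notch (0.02, 78.9) and stress lists (0.24, 93.8) lay further inside, and the circadian list (0.08) at 97.9, with a median of -0.15 in nuclei thinned to 1000 UMIs. Without a limit on the mitochondrial share the mitochondrially encoded median was 0.24, the opposite sign. The X-escape list had a median of -0.95 and the Y-linked list 5.96, and no percentile was computed for these 2 lists.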

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

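Each of the 6 tests of an explanation in this part was chosen only after the pattern it bears on was seen, and its prediction was written before the test was run.

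Grm8, an age-related hearing loss gene outside the rule for named genes and named here after its values were seen, counts among the 4 age-related genes higher in stria (log2 fold change -1.05, adjusted p = 0.0411 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) but moved in opposite directions in the 2 libraries: its log2 ratio of sensory epithelium to stria was 0.31 in the male and -1.40 in the female library. The difference was not tested, because each sex had 1 library.

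Pituitary and neuronal transcripts stood in near-empty droplets, which the comparisons do not use, above the limit that a count of 0 allows. Prl reached 48.9 CPM in the male and 341.1 CPM in the female library, Gh, the gene of growth hormone, 48.4 and 197.3 CPM, and Bc1 545.2 CPM in the female library. Of 9 further pituitary genes, 3 (Pomc, Scg2 and Pcsk1n) were higher in the female near-empty droplets with intervals that did not overlap, as pituitary tissue in the female pool predicted, although neurons express these genes too. The intervals of Cga, Pou1f1, Tshb, Lhb, Fshb and Chga overlapped. The summed level of 12 brain neuron genes was 1.90 times higher in the female library (1.69 to 2.14), as brain tissue in that pool predicted. Snap25 alone gave 346 of the 677 female and 295 of the 526 male UMIs. It is also on the neuron marker list used for naming, so this sum does not tell neurons of the cochlea apart from brain neurons. Pituitary and brain tissue may both contribute, and sex stays open and untested.

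Of 28 age-related hearing loss genes, 12 were higher in the sensory epithelium and 4 in stria, and the list call was lost with an estimated correlation (camera adjusted p = 0.0665). Gene length bias of nuclear RNA is argued against: the list median of 1.03 lay at percentile 100 of 10000 lists matched on expression and length. Hair cell nuclei alone are argued against as well, since 10 list genes were higher and 4 lower with the hair cell class left out. No biological explanation was tested.

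Hereditary deafness genes stood lower in the male library, where the list median lay at percentile 0 of the matched lists. That percentile already has the 0.5 added counts scaled to each sum, and a flat 0.5 moved the median only from -0.21 to -0.20, so it is no test of the added count. With each gene read only in the class where it was highest, the median was -0.14, between the 2 bounds set for free RNA taken up by all droplets. Free RNA therefore cannot be told apart from other causes here. No percentile was computed for that reading, and the matched lists did not account for how few classes express a gene. Sex stays open and untested, with 1 library each.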

How the results depend on the processing

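The alternatives that left out the hair cell class, added the supporting cluster kept out by the naming rule, summed the classes of a side before the test, added a flat 0.5 counts, or read each gene in its highest class only were chosen after seeing the data. Of 75 named gene results, 53 kept their call under every alternative run, 22 lost it under some and 0 changed direction. Without the library term the counts over all genes were 1872 higher and 2019 lower in the first contrast and 1378 and 908 in the second, and among the named genes only Npas2 lost its call, in hair cells. For each library alone, the list medians of the first contrast ranged from 1.01 to 1.05 (age-related) and from 0.82 to 0.86 (deafness), and those of the second from 0.67 to 0.78 and from 0.46 to 0.69, without a test. Values without a test were held against the SD of the 2 libraries (list medians), the SD over classes (male to female) or the binomial interval (shares). By the first of these measures, 39 alternative values of the 4 list medians counted as the same, 34 as moved and 1 as reversed. The alternatives for inner against outer hair cells were not run, since the class was too small. The inner border and phalangeal cell-like class did not form with at least 1000 detected genes, without a mitochondrial limit or with all variable genes used for clustering, nor the macrophage-like class at resolution 0.5; they have no share there, and the contrasts used the remaining classes. What depth limits was not tested apart from the thinning of the male to female values. Where a cause is not given below, the cause was not tested.

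In the sensory epithelium against stria, with the hair cell class left out, the deafness median was -0.0048 (0.66 before). The counts higher were 1 for mechanotransduction, 5 for stereocilia, 1 for ribbon synapse and 0 for sex hormone genes, and the counts lower 1 for mechanotransduction, 2 for stereocilia, 3 for ribbon synapse and 2 for circadian genes. With the classes of a side summed, the counts higher were 4 for mechanotransduction, 7 for ribbon synapse and 3 for circadian genes, and the counts lower 1 for stereocilia, 1 for ribbon synapse, 2 for Notch and 3 for circadian genes. With the supporting cluster added, 4 mechanotransduction genes were higher and 2 Notch genes lower. With at least 300 detected genes, 4 mechanotransduction genes and 1 stress gene were higher, and 2 Notch and 3 circadian genes lower. With at least 1000, 8 ribbon synapse and 3 Notch genes were higher, and 3 potassium, 2 Notch and 0 stress genes lower. Without a mitochondrial limit, 4 mechanotransduction, 8 ribbon synapse, 3 Notch and 12 mitochondrially encoded genes were higher, and 2 age-related, 3 potassium, 3 Notch and 2 stress genes lower. With all variable genes, 8 ribbon synapse and 3 Notch genes were higher, and 3 potassium, 1 tectorial membrane, 2 Notch, 1 X-escape and 3 circadian genes lower. Without doublet removal 3 Notch genes were lower, with library size only 2, and at resolution 0.5 1 ribbon synapse gene was. Without the expression filter, 1 ribbon synapse, 3 circadian and 2 stress genes were lower. With 10% free RNA subtracted, 1 mechanotransduction gene was higher and 7 deafness genes lower.

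In hair cells against supporting cells, no circadian gene (0) was higher with at least 1000 detected genes, without a mitochondrial limit, with all variable genes, with genes centred within libraries, without the library term, with summed classes, with free RNA subtracted or by DESeq2. The circadian genes lower were 3 with library size only, 2 with free RNA subtracted and 3 by DESeq2. Sex hormone genes higher were 2 without a mitochondrial limit, at resolution 0.5, with all variable genes and without the expression filter, and 1 was lower without doublet removal and without the filter. Without a mitochondrial limit, 2 tectorial membrane genes and 1 antioxidant gene were lower and 12 mitochondrially encoded genes higher. The last count was 2 with at least 300 genes, and 1 with centred genes, the supporting cluster added, DESeq2 size factors or DESeq2. With free RNA subtracted, 1 stress gene was higher.

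Among list tests, an estimated correlation gave adjusted p values of 0.0665 for age-related genes (first contrast) and 0.0737 for both Notch and circadian genes (second contrast). Fry, which tests a list by itself, gave directional and mixed values, in the first contrast, of 0.000102 and 1.63e-10 for ribbon synapse, 1.17e-05 and 3.93e-10 for potassium, 0.0249 and 0.0492 for sex hormone, and 0.00377 and 7.19e-12 for circadian genes, and a mixed 9.71e-06 for Notch genes. In the second they were 0.00194 and 6.03e-09 for potassium, 0.0363 and 0.000218 for sex hormone genes, and a mixed 3.86e-07 for antioxidant genes.

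The shares in percent, male then female where both moved, were as follows. With at least 300 detected genes Deiters and pillar cell-like nuclei were 4.69 and 6.30, and with the supporting cluster added 4.80 and 6.36. With at least 1000, fibrocyte-like were 6.82 and 8.83, Hensen and Claudius cell-like 3.485 and 5.16, and interdental cell-like 10.15 and 8.12. Without a mitochondrial limit, Hensen and Claudius cell-like were 2.86 and 4.86, and in the male library interdental 10.5, intermediate 4.88, marginal 3.94, Reissner's membrane 7.175 and unnamed 46.7. At resolution 0.5, fibrocyte-like were 8.01 and 9.99, Hensen and Claudius cell-like 3.04 and 4.75, unnamed 29.6 and 33.2, male basal cell-like 5.85 and female glia-like 5.29. At resolution 2.0, interdental were 7.53 and 7.37, and unnamed 42.0 and 44.7. With all variable genes, Hensen and Claudius cell-like were 8.54 and 9.72, and unnamed 35.0 and 38.3. Of age-related genes, 1 was highest in stria at resolution 0.5. Thinned to 1000 UMIs, the male to female median was 4.03 for Y-linked and -0.15 for circadian genes, and the mitochondrially encoded median was 0.24 without a mitochondrial limit and -1.67 with free RNA subtracted.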

Other observations

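Some of the clusters left without a name are given here as values, chosen after their values were seen. A cluster led by Rarres1 and Emilin2, which mark cells under the basilar membrane, held 180 male nuclei (7.92%) and 34 female nuclei (1.82%). It is the larger of the 2 clusters given above as closest to the fibrocyte list. A cluster with haemoglobin genes, Nefl, Calb2 and Prl among its leading genes held 42 male (1.85%) and 133 female barcodes (7.10%). It had a median of 2339 UMIs and 2.31% mitochondrial UMIs, and its female barcodes had 390 UMIs of Prl and 256 of Gh. The naming rule refused this cluster as haemoglobin RNA without a nucleus, so it cannot be counted as a cell group. Whether its barcodes hold nuclei or free RNA was not tested. A small cluster rich in Kcnd2 and Grin2a, genes of neuronal ion channels, held 1 male (0.0440%) and 33 female nuclei (1.76%), whose female nuclei had 592 UMIs of Kcnd2 and 442 of Bc1. Another unnamed cluster closest to the neuron list, led by Cntnap5a, held 13 male and 23 female nuclei. Its intervals overlapped (0.305% to 0.9765% and 0.7804% to 1.838%). A cluster without a candidate list, led by Folh1 and Slain1, held 99 male (4.36%, 3.56% to 5.28%) and 154 female nuclei (8.23%, 7.02% to 9.56%). Another, led by Fst and Fgf9, held 48 male and 68 female nuclei. Both had Lgr5, which is on the Deiters and pillar cell marker list, among their first 10 genes. Whether they hold supporting cells was not tested.

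The male to female median of deafness genes differed between classes. It was -1.10 in intermediate cell-like, -0.74 in basal cell-like, -0.36 in fibroblast-like, -0.13 in hair cell-like and 0.03 in Deiters and pillar cell-like nuclei, and the other classes lay between -0.36 and 0.03. So 2 classes, intermediate and basal, had the largest shifts. These classes also had the lowest medians over all 11894 genes, -0.30 and -0.18. In intermediate cell-like nuclei the other lists outside the Y-linked and X-escape genes ranged from -2.36 (tectorial membrane) to -0.09 (circadian), with antioxidant genes at -0.45 and sex hormone genes at -0.68.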
